A study of Danio rerio with 60 samples.

How the data were processed

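Gene expression was measured by RNA sequencing in zebrafish larvae of the AB/Tub background. Each of the 60 samples was RNA from 20 whole larvae pooled, so a sample mixes all tissues of the larva. Larvae were kept with the test substance in buffered E3 medium from 72 to 120 hours post-fertilization and then frozen. Per the labels' protocols, total RNA was purified on columns with DNase treatment, and libraries came from a stranded, poly(A)-selecting Illumina kit. Raloxifene, a selective estrogen receptor modulator, was given at 20.1, 2.01, 0.201, 0.0201 and 0.00201 µM beside a 0.5% carrier control. Resorcinol, a small phenol known to inhibit thyroid peroxidase, was given at 405, 40.5, 4.05, 0.405 and 0.0405 µM beside a 1% carrier control. The carrier is not named in the sources used here. Each of the 12 groups held 5 samples. Both the titles and the treatment labels of the dosed resorcinol samples carry the short name of raloxifene. These samples were grouped by their description, which names resorcinol and the dilution. For both compounds the descriptions mark the highest dose as EC20 and its control as CC20. They do not explain these marks or name an effect.

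The authors deposited 2 tables, 1 per compound, of read counts per Ensembl gene divided by 1 factor per library, a signal that is never negative. These normalized counts are the values used here. Per the submitters' processing notes, reads were handled with cutadapt, STAR and DESeq2 on GRCz11, with no versions, parameters or order given. The counting tool, its strand setting and the annotation release are not given in the sources used here. Whole reads were recovered for 100% of the values at a tolerance of 0.1 read. The recovered depth was 7.44 to 10.98 M reads in the raloxifene libraries, median 9.54 M. In the resorcinol libraries it was 7.78 to 12.1 M, except 405 µM replicate 1 at 30.7 M. The tables held 27281 and 27488 genes. Because they were normalized separately, levels were compared only within 1 compound, and only calls and fold changes were compared between compounds. No pair of libraries of the same group agreed within sampling noise: the lowest chi-square per degree of freedom was 4.00. Pairs across groups were not compared.

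Gene symbols came from a reference name table that matched 24960 of the 27281 and 25126 of the 27488 identifiers. Many of its symbols are human-style capitals shared by duplicated zebrafish genes (3751 and 3824 identifiers share a symbol), so identifiers are printed where a symbol is shared. Where duplicated genes share near-identical sequence, the division of reads between them is uncertain. No genome was used, so no coordinates are given.

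Differential expression was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(normalized count + 1). Fold changes are on that scale, which understates the change of low genes. All 30 libraries of a compound entered 1 fit with 6 group means, so that all groups share 1 estimate of the spread. Genes needed a normalized count of at least 10 in at least 5 libraries. This left 19241 genes for raloxifene and 19583 for resorcinol. Benjamini-Hochberg adjusted p under 0.05 made a call, and adjusted p values below are of this kind. The comparisons, lists and alternatives were fixed before the data were examined, for raw counts. The deposited unit required limma in place of a count model, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

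The labels give each group replicates 1 to 5. Whether these numbers mark a shared clutch, plate or day is not stated. The pairing was therefore checked in the data, from each library's deviations from its group mean. All 75 same-number pairs per compound correlated at more than 0.1, with a lowest r of 0.344 for raloxifene and 0.194 for resorcinol. The replicate number accounted for 77.2% and 69.1% of the variance of all genes, against 5.53% and 6.83% for the group. The numbers were therefore taken to pair the samples. A fit with the replicate number as a block was run for every result, and its value is given where it changes a call or moves a count by over 1.5 times. The block lowered the median standard error from 0.304 to 0.155 log2 units for raloxifene and from 0.277 to 0.154 for resorcinol. The fit chosen at first had no block. The labels do not say whether replicates came from separate spawnings, so p-values measure the spread between these pools.

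On simulated data with the real levels and spread, the fit without the block recovered 23.0% of 2-fold changes for raloxifene and 26.0% for resorcinol. It recovered 6.06% and 2.02% of 1.5-fold changes, with 0 false calls among the unchanged genes. With the block it recovered 63.0% and 74.0% of 2-fold changes and 48.5% and 41.4% of 1.5-fold changes, with 7 and 6 false calls. An undetected change of this size is therefore not an absent one.

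Genes were named by a rule fixed at the same time. At the highest dose it takes the 10 largest rises and 10 largest falls with a symbol, adjusted p under 0.05 and no overlap between the 5 treated and 5 control libraries. At lower doses it takes 3 each way. It adds up to 4 called members of each gene list, the 5 lowest benchmark doses and a fixed set of endocrine genes. Of these, the thyroid peroxidase gene had no match in the name table, and cyp1a was matched afterwards as CYP1A1. For the blocked fit a like rule was chosen after the data were seen, which asks for all 5 pairs in 1 direction in place of no overlap, so treated and control libraries of these genes can overlap. Not every gene that the rule names is printed. Other genes were named after their values were seen, and the text says where. Gene lists for pathways, tissues and cell types (36 lists, 959 entries, 34 with at least 5 tested members) were fixed beforehand. Of the entries, 687 matched by symbol, 14 by a RefSeq synonym, 196 by a human-style symbol and 62 not at all. Lists were tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists and doses of a compound.

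Dose response was tested with an F test over all doses. Genes with adjusted p under 0.05 and a change of at least 1.5-fold were fitted with dose-response curves. Fits with a lack-of-fit p under 0.1 were left out. The benchmark dose is where the curve left the control by 1 SD. On simulated curves, 174 of 200 gave a benchmark dose, with a median ratio to the true dose of 1.12. Those curves were large relative to their noise, had a shape among those fitted and held no replicate effect. The ratio therefore does not give the accuracy for smaller changes in the real data. Medians carry 95% intervals from 100 bootstrap draws with the gene set fixed, so these leave out the variation in which genes pass. Without the block the draws did not keep the pairs. Alternatives covered the pseudocount, the level filter, quantile normalization, array weights, a fit on only the 2 groups compared, the count tools, the benchmark settings and leaving out each library or replicate number. Those for the blocked fit, and leaving out replicate numbers for counts across doses, benchmark doses and lists, were chosen after the data were seen.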

Results

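RNA from pools of 20 zebrafish larvae was sequenced after exposure to raloxifene or resorcinol from 72 to 120 hours post-fertilization. For each compound, 5 doses in 10-fold steps and a carrier control were measured with 5 pools each. Depth was 7.44 to 10.98 M reads per raloxifene library and 7.78 to 30.7 M per resorcinol library. The study compared each dose with the carrier control and asked at which dose expression departs from it.

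At 20.1 µM raloxifene, calcium-binding protein genes and odorant receptors made up 7 of the 8 genes that fell. The parvalbumin gene pvalb5 fell from a normalized count of 684 ± 59.21 to 194 ± 24.1 (SD, n = 5), which is 3.53-fold lower (limma, adjusted p = 2.93e-05). A second parvalbumin gene, pvalb8, fell from 2192 ± 421 to 943 ± 184, or 2.32-fold (adjusted p = 2.56e-04), and S100Z from 75.6 ± 9.31 to 28.3 ± 10.29, or 2.72-fold (adjusted p = 0.00167). The odorant receptors or93a1, or30bt3, or90d1 and or6at1 fell by 2.38, 2.17, 2.15 and 1.78 on the log2 scale, all from low levels, as for or93a1 at 7.66 ± 2.16. The cerebellin-like gene cbln20 fell by 1.33 (SE 0.25). In each of these genes all 5 pairs were lower and treated and control libraries did not overlap.

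Among the 10 genes that rose at 20.1 µM, si:dkey-7c18.24 went from 222 ± 105 to 1229 ± 341 (5.79-fold, adjusted p = 3.21e-04). The largest folds were in genes near the detection limit in controls, zgc:172053 (5.33 ± 3.86 to 75.3 ± 38.8) and si:ch211-213i16.3 (3.59 ± 2.34 to 41.5 ± 11.8). The vitamin B12 binding protein gene tcnbb rose 2.01-fold from 533 ± 144. HMGCS1, an early enzyme of cholesterol synthesis, rose 1.62-fold from 247 ± 37.2 to 400 ± 33.1 (adjusted p = 0.00602). The peroxiredoxin gene prdx1 rose 1.62-fold from 169 ± 10.1. The chemokine ccl33.3 (log2 2.66), the galectin lgals9l1 (1.22), si:ch211-183d5.2 (2.15) and zgc:195356 (1.70) completed the group.

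In all, 18 of 19241 genes passed at 20.1 µM without the replicate block, 10 higher and 8 lower, and 242 with it, 168 higher and 74 lower, including all 18. The 242 went to 147, 117, 129 and 137 without replicates 2, 3, 4 and 5, and to 149 with a 1.5-fold minimum. Quantile normalization left 11 calls, 8 of them higher, while a level minimum of 50 left 9, a fit on only the 2 groups left 3, array weights gave 122 and DESeq2 gave 28. Leaving out control replicate 3 or 20.1 µM replicate 2 left 11 calls. In the fits that each left out 1 library, pvalb5, pvalb8, S100Z, or93a1, or30bt3, zgc:172053, si:ch211-213i16.3, si:dkey-7c18.24, tcnbb and HMGCS1 kept their calls in 10 of 10. The calls of ccl33.3 and si:ch211-183d5.2 were lost in 9 of 10 (adjusted p up to 0.198 and 0.278), that of or6at1 in 8 of 10 and that of cbln20 in 6 of 10. Those of lgals9l1 and prdx1 were lost in 5 of 10, that of or90d1 in 3 of 10 and that of zgc:195356 in 1 of 10 (adjusted p up to 0.0524).

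With the block, all 10 odorant receptors that passed the level filter fell at 20.1 µM, against 4 without it. Summed over the 106 odorant receptor genes in the table, the level was 266 ± 24.6 in controls and 66.4 ± 19.0 at 20.1 µM, 4.12-fold lower, and lower in 5 of 5 pairs. The sums at 2.01, 0.201, 0.0201 and 0.00201 µM were 255 ± 43.1, 274 ± 57.3, 262 ± 74.9 and 243 ± 62.4. This set was chosen after the calls were seen. Receptor sequences were not compared, and the division of reads between any similar receptors is uncertain. The blocked fit also raised the chemokine cxcl19 (log2 2.44), PKHD1L1 ENSDARG00000040004 (2.08), COL10A1 (2.05), gstp1.1 (1.93) and arf4b (1.78), and lowered irge1 (-1.90).

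**Figure D1:**
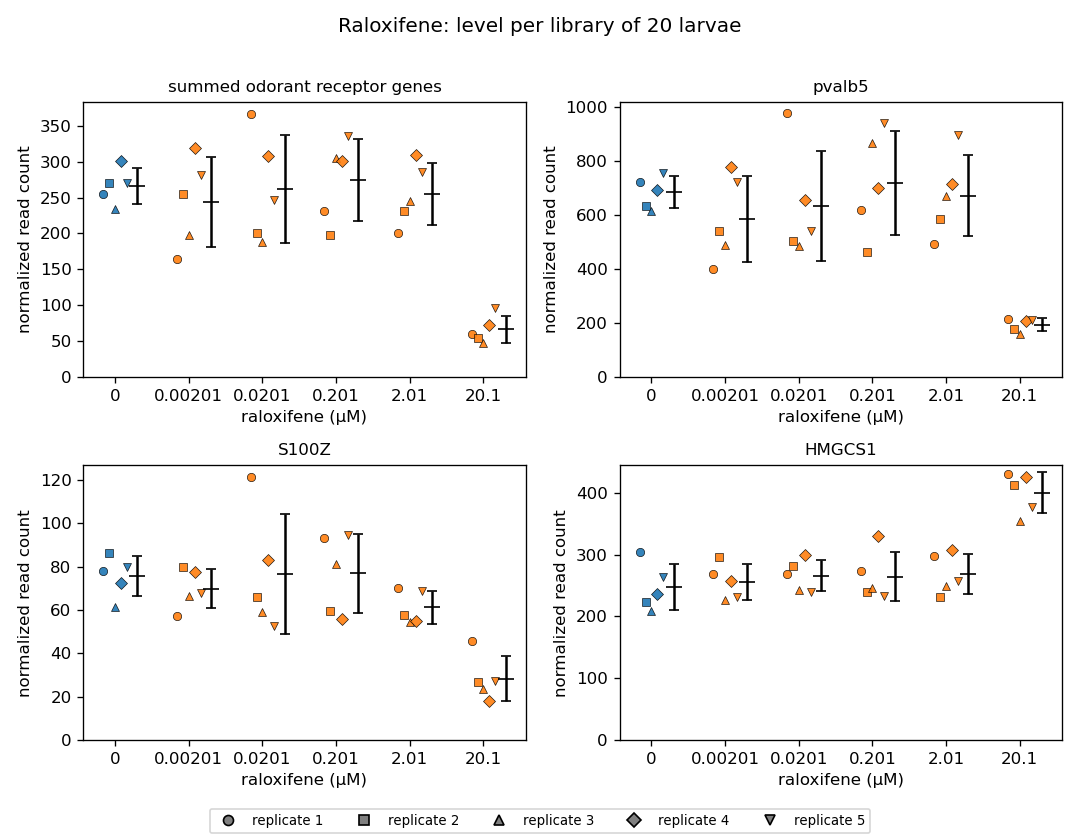
Normalized read count (vertical axis, from 0) against raloxifene dose in µM (horizontal axis, 0 is the carrier control) for the summed odorant receptor genes, pvalb5, S100Z and HMGCS1. Each symbol is 1 pool of 20 larvae, its shape gives the replicate number, and bars are mean ± SD (n = 5); the odorant receptor sums at 20.1 µM lie between 47.9 and 96.1, below the control range of 234 to 301.

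Among the gene lists fixed beforehand, lysosomal genes at 20.1 µM included 4 of 32 that rose over all genes tested with the block, and 6 adjusted over the list alone. They were the cathepsins CTSB (1.42-fold, adjusted p = 1.62e-07), ctsla (1.28-fold) and CTSD (1.25-fold), and the autophagy receptor SQSTM1 (1.65-fold). Of 25 cholesterol synthesis genes, HMGCS1 rose and 3 did so with the block adjusted over the list alone. Of 23 heat shock genes, hsp70.3 (2.70-fold) and HSPB1 (1.51-fold) rose with the block, and 6 adjusted over the list alone. Of 29 intestinal genes, FABP6 (1.91-fold lower), ANPEP ENSDARG00000103878 (2.06-fold lower) and MEP1B ENSDARG00000040683 (1.66-fold lower) fell and AGR2 (log2 1.32) rose with the block, with 11 lower and 1 higher adjusted over the list alone. Of the 16 inflammation genes, SOCS3 ENSDARG00000026611 (1.35-fold) and the matrix protease MMP9 (log2 1.07) rose with the block, 4 adjusted over the list alone. Single members with a blocked call in other lists included PDK2 (log2 0.75), agr1 (0.82), icn (0.47), slc12a10.2 (0.71), ctrl (0.99) and SLC20A1 (0.27) among the rises. Falls included kif11 (-0.48), FABP1 (from 935 ± 983 to 401 ± 321), uox (-0.99), lgals3bp.1 (-0.51), krt97 (-0.42) and pmelb (-0.56). The change of uox went to -0.19 without control replicate 4 and -1.92 without 20.1 µM replicate 4.

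As whole lists, camera with the preset correlation placed 12 of 34 higher and 3 lower at 20.1 µM, and 14 with the block. None passed with an estimated correlation (lowest adjusted p = 0.186 with an estimated correlation, 0.311 with the block), so no list is described as having risen or fallen. The list medians were 0.19 for heat shock (adjusted p = 0.186 with an estimated correlation), 0.11 for cholesterol synthesis (adjusted p = 0.235 with an estimated correlation) and 0.09 for lysosome (adjusted p = 0.818 with an estimated correlation). They were -0.42 for intestine (adjusted p = 0.930 with an estimated correlation) and -0.23 for cell cycle (adjusted p = 0.890 with an estimated correlation).

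Estrogen receptor and thyroid genes gave no call at 20.1 µM, with or without the block. Of the 4 tested genes on the estrogen response list, which include 2 of these receptors, CTSD was called with the block (1.25-fold higher, adjusted p = 0.00911). ESR1 was at 4.37 ± 2.14 in controls and 6.53 ± 5.41 at 20.1 µM, and ESR2 ENSDARG00000034181 at 25.6 ± 11.7 and 30.97 ± 8.33 (log2 0.32, SE 0.33). TG, the thyroglobulin gene, was at 6.38 ± 5.40 and 10.7 ± 7.80, DIO2 at 15.3 ± 6.06 and 14.9 ± 4.76, and CYP1A1 at 82.9 ± 87.2 and 98.97 ± 83.9. On the log2 scale DIO2 changed by 0.030, opposite in sign to its mean counts. That change turned negative without control replicate 4 (log2 -0.30), without 20.1 µM replicate 1 (-0.074) or 5 (-0.088), and with edgeR (-0.056), DESeq2 (-0.044) or a pseudocount of 10 (-0.0054). The vitellogenin gene vtg1, CYP19A1, ESR2 ENSDARG00000016454 and TSHB stayed under the level filter, and vtg1 reached at most 3.00 in any library. Genes under the filter were not tested.

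At the lower raloxifene doses limma called 0 genes at 2.01, 0.201, 0.0201 and 0.00201 µM. Unadjusted p fell under 0.05 for 164, 112, 60 and 222 genes, where evenly spread p values would give 962. This fit leaves out the pairing, so its p values run high and 962 does not hold for it. edgeR and DESeq2 on recovered reads, also without the block, called 0 at each. With the block, 4, 3, 0 and 19 genes passed with limma, 4, 5, 0 and 8 with edgeR and 22, 52, 0 and 185 with DESeq2. Unadjusted p then fell under 0.05 for 1897, 1864, 1013 and 2678 genes, all above 962, though genes are not independent. At 20.1 µM that last count was 2363 with the block, below the 2678 at 0.00201 µM, so it did not follow the dose. In the limma fit with the block si:dkey-227h16.2 was lower at 2.01 µM (1.85-fold), 0.201 µM (1.94-fold) and 0.00201 µM (1.72-fold), and the gene ENSDARG00000089004 higher at 0.201 µM (from 15.6 ± 7.05 to 34.4 ± 7.63) and 0.00201 µM (log2 1.26). At 2.01 µM si:ch73-329n5.6 (1.79-fold) and si:dkey-247k7.2 (1.67-fold) were higher, and at 0.201 µM si:ch211-196l7.4 was lower (1.24-fold). At 0.00201 µM agbl1 and GMPR were higher (2.29-fold and 2.22-fold, the latter 3.54-fold without control replicate 4), and the neuronal transcription factor genes POU4F1 and TBR1 lower (1.36-fold each). The 19 calls at 0.00201 µM went to 1, 0, 0, 10 and 12 without replicates 1 to 5. The 4 at 2.01 µM went to 0, 2, 1 and 1 without replicates 1, 3, 4 and 5, and the 3 at 0.201 µM to 0 without replicate 1, 2, 3 or 4 and to 8 without replicate 5.

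At 405 µM resorcinol, the genes that fell included a cone opsin and photoreceptor guanylate cyclase activators. The green cone opsin gene opn1mw2 fell from 750 ± 315 to 88.9 ± 27.1 (SD, n = 5), 8.15-fold lower (limma, adjusted p = 0.0253). GUCA1A ENSDARG00000100747 fell from 109 ± 31.4 to 16.46 ± 3.87 (6.16-fold, adjusted p = 0.00299) and guca1d from 44.0 ± 14.5 to 7.55 ± 3.18 (5.31-fold, adjusted p = 0.0253). The transcription factor gene nfil3-6 fell from 1322 ± 412 to 242 ± 85.3 (5.53-fold), and FHL2 ENSDARG00000003991 3.91-fold to 22.3 ± 6.20 (adjusted p = 0.0344). The remaining call, si:dkey-61n16.5, rose by a log2 of 1.32, from 324 ± 103 to 829 ± 317 in 5 of 5 pairs, with overlapping groups.

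These were the 6 of 19583 genes that passed at 405 µM, 1 higher and 5 lower. With the block 64 passed, 34 higher and 30 lower, including all 6, while array weights gave 12 and DESeq2 gave 16 (130 with the block). The 64 went to 11, 13 and 27 without replicates 1, 2 and 5. GUCA1A ENSDARG00000100747 kept its call in 10 of 10 fits that each left out 1 library. The count went to 1 without control replicate 1, 2 or 3 or 405 µM replicate 1 or 3, and to 2 without control replicate 4 or 405 µM replicate 5. Without control replicate 5 or 405 µM replicate 4 it went to 4. The calls of opn1mw2, nfil3-6 and guca1d were lost in 7 of the 10 (adjusted p up to 0.111, 0.115 and 0.115), si:dkey-61n16.5 in 8 and FHL2 in 9.

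With the block, heme oxygenase HMOX1 rose 2.83-fold at 405 µM (34.1 ± 9.39 to 97.5 ± 22.3, adjusted p = 1.20e-04; 0.0904 without the block). Other rises with the block were cyp2k6 (4.17-fold), RDH8 ENSDARG00000099217 (3.39-fold, or 1.90-fold without control replicate 1, where it was 0), gch2 of pteridine pigment synthesis (2.35-fold), CNGA3 ENSDARG00000012297 (1.90-fold), tmem130 (1.87-fold) and a second GUCA1A gene, ENSDARG00000101567 (2.68-fold). Falls with the block were STXBP4 (3.48-fold), guca1g (3.03-fold), si:ch211-276a17.5 (2.98-fold), C20H6orf58 (2.90-fold, or 4.38-fold without control replicate 4) and pak6b (2.76-fold). The thyroid hormone receptor gene THRA ENSDARG00000000151 fell 2.63-fold with the block, from 175 ± 43.6 to 65.5 ± 16.45 (adjusted p = 0.00119; 0.0931 without). Its duplicate ENSDARG00000052654 was at 58.1 ± 12.8 and 37.9 ± 13.6 (adjusted p = 0.184 with the block). TG, DIO2, CYP1A1 and ESR2 ENSDARG00000034181 gave no call (log2 -0.38, 0.28, 0.25 and 0.14, the last turning to -0.10 without control replicate 1 and -0.0045 without 405 µM replicate 3), and ESR1, vtg1, CYP19A1 and TSHB were under the level filter.

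**Figure D2:**
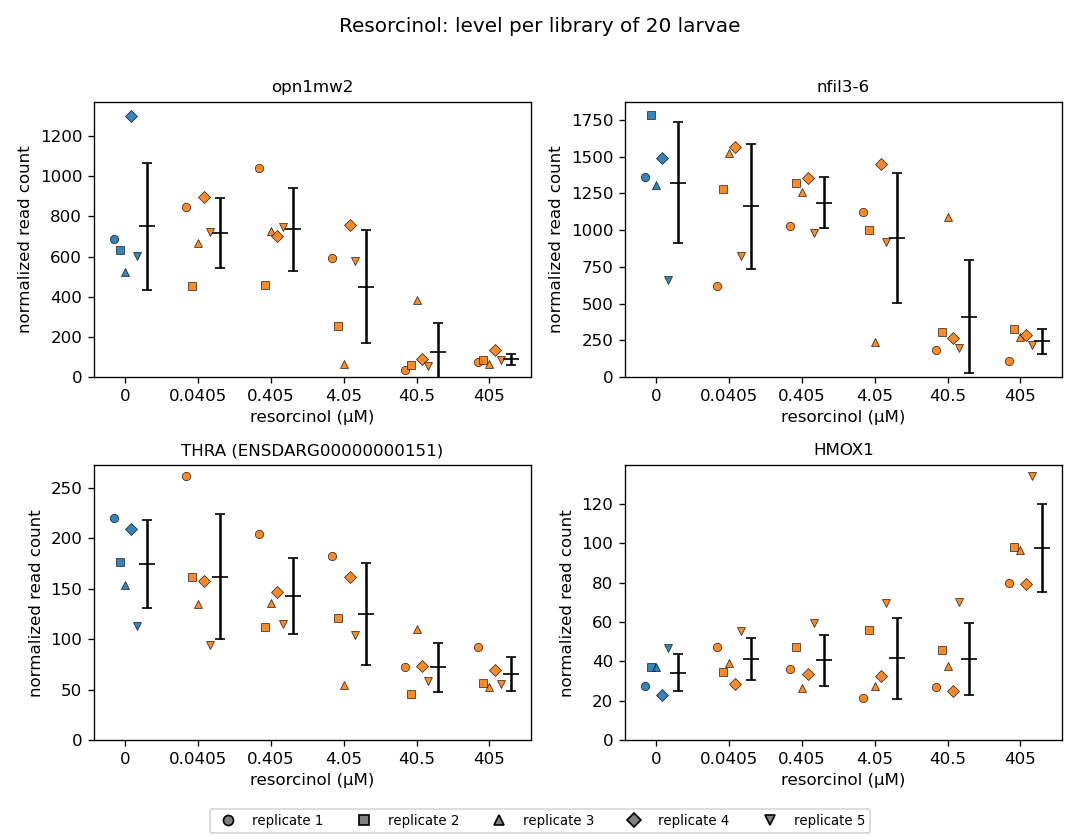
Normalized read count (vertical axis, from 0) against resorcinol dose in µM (horizontal axis, 0 is the carrier control) for opn1mw2, nfil3-6, THRA ENSDARG00000000151 and HMOX1. Each symbol is 1 pool of 20 larvae, its shape gives the replicate number, and bars are mean ± SD (n = 5), clipped at 0; in the first 3 panels replicate 3 (upward triangles) is low at 4.05 µM and high at 40.5 µM relative to the other 4 pools, as for opn1mw2 at 66.5 and 383.

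Of 44 photoreceptor genes on the list fixed beforehand, 2 fell at 405 µM, and with the block 2 fell and 4 rose. Adjusted over the list alone, 2 rose and 2 fell without the block, and 8 rose and 5 fell with it. The rises with the block included GRK7 ENSDARG00000055534 (1.71-fold) and gnb3b (log2 0.58), a kinase and a G protein subunit of cones. Of 28 digestive enzyme genes of the exocrine pancreas, those that rose with the block included CEL ENSDARG00000017490 (2.18-fold), and 24 rose adjusted over the list alone. The list median was 0.93 (adjusted p = 0.991 with an estimated correlation). Of 26 drug metabolism and transport genes, cyp2k6, UGT1A1 (1.71-fold) and cyp2k18 (1.64-fold) rose with the block, and 8 adjusted over the list alone. Of 22 oxidative stress genes, HMOX1 and prdx1 (1.81-fold) rose with the block, and 4 adjusted over the list alone.

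Camera placed 5 of 34 lists higher and 1 lower at 405 µM with the preset correlation, and 10 in all with the block. None passed with an estimated correlation (lowest adjusted p = 0.168 with an estimated correlation, for the thyroid axis list, whose median was -0.28). The lens genes had a median of 1.02, with 32 of 32 above 0 and no single call (adjusted p = 0.991 with an estimated correlation).

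At 40.5 µM resorcinol, opn1mw2 was the single call, at 750 ± 315 in controls and 123 ± 146, 8.58-fold lower (adjusted p = 0.0392). The call was lost without any 1 of the 5 controls or of 40.5 µM replicates 1, 2, 4 and 5, and also with edgeR, array weights or only the 2 groups. Without 40.5 µM replicate 3, 9 genes passed. With the block 13 passed, among them guca1d (4.36-fold lower), GUCA1A ENSDARG00000100747 (4.26-fold lower), THRA ENSDARG00000000151 (log2 -1.29) and si:dkey-61n16.5 (1.88-fold higher). That count went to 0 without replicate 1, 2, 4 or 5 and to 42 without replicate 3.

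Over 27 other genes that fell at 405 µM with the block, the median log2 change from the same-numbered control was -0.14 in 40.5 µM replicate 3, against -1.09 to -0.74 in the other 4 libraries. In 4.05 µM replicate 3 it was -0.70, against -0.29 to 0.03 in the other 4. Both replicate 3 libraries thus lay outside their own group, and the mean levels at 4.05 and 40.5 µM include them as labelled.

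At 4.05, 0.405 and 0.0405 µM resorcinol, limma called 0 genes, with 91, 61 and 177 at an unadjusted p under 0.05. Evenly spread p values would give 979, which does not hold for this fit without the pairing. edgeR and DESeq2 on recovered reads also called 0. With the block limma called 0 at each, with 762, 577 and 1684 genes at an unadjusted p under 0.05, and DESeq2 called 1 at 0.0405 µM. The change of opn1mw2 at 4.05 µM was -1.07, that of GUCA1A ENSDARG00000100747 -0.71 and that of nfil3-6 -0.62, none of them called. These changes include 4.05 µM replicate 3, which was the lowest library for each gene, as for opn1mw2 (66.5, others 253 to 755).

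Across all doses, the F test called 15 genes for raloxifene and 8 for resorcinol, and 352 and 44 with the block. The 15 raloxifene genes had a median benchmark dose of 5.02 µM (95% bootstrap interval 2.48 to 5.79), with 11 of them above 2.01 µM. The lowest were si:dkey-7c18.24 at 1.11 µM, tcnbb at 1.36, si:ch211-213i16.3 at 1.42, zgc:172053 at 1.74 and or30bt3 at 4.36. With the block 116 genes had a benchmark dose, median 6.04 µM (4.36 to 6.15), the lowest 0.154 µM for si:ch211-39f2.3, with 28 of the 116 under 2.01 µM. The 8 resorcinol genes had a median of 4.54 µM (1.21 to 10.6), all under 40.5 µM. The lowest were si:ch211-276a17.5 at 2.56 µM, opn1mw2 at 2.58, guca1d at 2.95, KCNV2 ENSDARG00000062906 at 3.36 and GUCA1A ENSDARG00000100747 at 5.71. With the block there were 36, median 4.52 µM (1.51 to 6.81), 34 of them under 40.5 µM. These doses are for a change of 1 SD, and for 2 SD the medians without the block were 10.03 µM for raloxifene and 11.37 µM for resorcinol.

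These counts moved with single replicate numbers. Leaving out numbers 1 to 5 in turn left 9, 3, 6, 10 and 2 raloxifene genes with a benchmark dose, with medians of 3.58 to 4.47 µM. For resorcinol it left 0, 0, 10, 0 and 2, with medians of 4.26 to 5.08 µM where any gene was left. Without the highest dose no gene of either compound had a benchmark dose.

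Neighbouring doses share their controls. Across genes, which are not independent replicates, the fold changes at the 2 highest doses correlated at r = 0.481 (rho 0.483) for raloxifene and 0.506 (rho 0.431) for resorcinol. Simulated unchanged groups against the same controls gave 0.499 for both. The covariance was 0.0345 against a simulated 0.0252 for raloxifene and 0.0294 against 0.0218 for resorcinol. With separate controls, split 2 against 3, the median r was 0.0626 and 0.0846.

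Between compounds, no gene was called at both 20.1 µM raloxifene and 405 µM resorcinol without the block, among 19058 genes tested in both. With the block, si:dkey-61n16.5, prdx1 and the lipase gene LIPG were higher with both, against 0.287 given by independent lists (Fisher's exact test, p = 0.00292, two-sided). None was lower with both, against 0.110 from independent lists of 70 and 30. Across genes the fold changes correlated at r = 0.194 (rho 0.194), and the 2 compounds had separate controls and carrier shares.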

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

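The tests on an unusual control group, on the circadian clock, on thyroid hormone, on replicate 3 of resorcinol 4.05 and 40.5 µM and the counts of splits were chosen after the result was seen. The others below were written down first.

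In the following groups of 5, the gap from 1 library to the nearest of the others took more of the group's range than Dixon's critical value of 0.71. Chance gives this in about 1 in 20 groups. It was seen in 4 of 36 library measures and 12 of 193 gene groups (6.22%). The share of reads in the 10 most abundant genes was 18.6% in raloxifene 20.1 µM replicate 2 (others up to 14.5%), 18.2% in resorcinol 0.0405 µM replicate 1 and 16.2% in resorcinol control replicate 4 (others up to 14.3%). The share was as high in replicate 2 of every raloxifene group (mean 18.8%), so it was not particular to 20.1 µM. Resorcinol 405 µM replicate 1 held 30.7 M reads against 8.98 to 12.1 M.

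Among the genes, raloxifene replicate 4 stood apart for si:dkey-227h16.2 (34.6 at 0.00201 µM and 22.9 at 2.01 µM), agbl1 (31.2 at 0.00201 µM), si:ch211-196l7.4 (513 at 0.201 µM), uox (360 at 20.1 µM, others 6.97 to 20.48, and 488 in the control, others 18.6 to 45.3) and DIO2 (5.05 in the control). Other single libraries were zgc:172053 in 20.1 µM replicate 1 (13.7, others 65.3 to 116), or30bt3 in 20.1 µM replicate 2 (0), tcnbb in control replicate 2 (787) and or70a5 in control replicate 1 (1.42). In resorcinol it was RDH8 ENSDARG00000099217 in control replicate 1 (0, others 14.8 to 20.3).

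Odorant receptor genes were lower at 20.1 µM raloxifene. The other genes at their level had a median log2 change of 0.025, which cannot test lower depth, since the values were already scaled for depth. Lower depth is argued against by the recovered reads, compared afterwards. The 20.1 µM libraries held 7.44 to 10.22 M reads and the control libraries 7.64 to 10.29 M. Reads moved between copies are argued against by the summed level of all receptors, at -2.04. Fewer olfactory neurons stays open: 16 further markers had a median of -0.073, above the bound of -0.25 set beforehand, but that list left out 3 genes already called lower, and of all 19 (median -0.080) the 4 called ones changed by -1.82 to -1.04, while OMP changed by -0.20 and the rest may also be expressed in other tissues of the pools. Fewer hair cells stays open as well. The 36 further markers (median -0.18, 28 below 0, 2 called lower with the block) also left out 3 called genes. With those, 31 of 39 were below 0 (median -0.27) and 5 were called lower. Lower expression per cell cannot be told apart from fewer cells in pools of whole larvae.

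The 30 genes lower at 405 µM resorcinol with the block had a median log2 change of -1.04. Without replicate 1, which holds the deep library, the median was -0.95. The genes were chosen with that replicate included, so this cannot decide how far the calls rest on it. Without replicate 1 the 64 calls with the block became 11, the fewest over single replicates (11 to 58). An unusual control group is argued against by -0.88 against the 2 lowest doses. A shift of the circadian clock stays open: the median absolute change of the clock genes other than nfil3-6 lay at percentile 45.8 of random lists, but that list left out nfil3-6, which was called lower. Less thyroid hormone signal stays open: of 5 genes taken as raised by the hormone, 1 (THRA ENSDARG00000000151) was called lower. Not called at 405 µM were THRA ENSDARG00000052654 (log2 -0.66), dio3b (-1.29), THRB (-0.06) and KLF9 (0.26). Across doses dio3b did pass the F test with the block, with a benchmark dose of 3.59 µM.

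In replicate 3 of resorcinol 4.05 and 40.5 µM, 27 lower genes outside the plotted opn1mw2, nfil3-6 and THRA had median log2 changes of -0.70 and -0.14 from the same-numbered control. A stronger response of 4.05 µM replicate 3 alone is argued against by the -0.14, since the other 4 libraries at 40.5 µM ranged from -1.09 to -0.74. An exchange of these 2 libraries may be the cause. The -0.14 lay within the range of the other 4 at 4.05 µM (-0.29 to 0.03). The exchange stays open by this test only because -0.70 falls just short of the range at 40.5 µM. In opn1mw2, nfil3-6 and THRA, left out of the test, each library lay within the range of the other group. For opn1mw2 these were 66.5 (others at 40.5 µM 34.3 to 87.8) and 383 (others at 4.05 µM 253 to 755). No library was relabelled, so the calls at 40.5 µM and the resorcinol benchmark doses include both as labelled. Neither was recomputed with the 2 exchanged.

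Other splits of the samples were counted for each count of calls, and each total of 100 or 50 includes the labelled split itself. At 20.1 µM raloxifene, 1 of 100 splits called at least the 18 genes (highest other 1). Only 11 of the other splits parted all 5 pairs, as the labelled one does. These called 0 but are too few to show chance to be unlikely. With the block, chance is unlikely for the 242 calls (1 of 100, highest other 1). Swaps within pairs allow only 16 splits, of which 1 called as many (highest other 11). With the block, chance is also unlikely for the 352 genes across doses (1 of 100, highest other 3) and the 116 with a benchmark dose (1 of 100, highest other 0). Without it, 1 of 100 relabellings gave at least the 15 genes across doses (highest other 2) and the 15 with a benchmark dose (highest other 0). Those relabellings did not keep the replicate numbers, so they are no like comparison. For the lists chance stays open: 9 of 50 splits called at least the 15 lists (highest other 21), and 3 of 50 at least the 14 with the block (highest other 16). For the 0 calls at 2.01, 0.201, 0.0201 and 0.00201 µM all 100 splits gave as many, with highest others of 2763, 0, 0 and 0. The split with 2763 parted fewer pairs, which points to the replicate structure; the splits that parted all 5 pairs called 0. With the block, 2, 2, 100 and 1 of 100 gave at least the 4, 3, 0 and 19 calls, with highest others of 357, 4, 25 and 6. By the same measure chance is unlikely for the 19 calls at 0.00201 µM, and unlikely but not excluded for the 4 and the 3. Passing this count therefore did not follow the dose, and the 19 went to 0 without replicate 2. The relabelling with 357 points to a structure of the samples, whose source was not examined.

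At 405 µM resorcinol, 1 of 100 splits called at least the 6 genes, and a split parting fewer pairs gave 5. Only 11 of the other splits parted all pairs, and these called 0 but are too few to show chance to be unlikely. For the 64 with the block chance is unlikely but not excluded, since 1 other relabelling gave 89 (2 of 100). Of the 16 splits by swaps within pairs, 1 called as many (highest other 0). For the lists chance stays open: 36 of 50 splits gave at least the 6 lists (highest other 23) and 3 of 50 at least the 10 with the block (highest other 11). At 40.5 µM chance is unlikely for the 13 calls with the block (1 of 100, highest other 1). For the 1 call without it, 1 of 100 splits gave as many (highest other 0), but only 12 others parted all pairs. At 4.05, 0.405 and 0.0405 µM all 100 splits gave at least the 0 calls, with highest others of 0 without the block and 33, 16 and 7 with it. With the block, chance is unlikely for the 44 genes across doses (1 of 100, highest other 1) and the 36 with a benchmark dose (1 of 100, highest other 0). Without it, 1 of 100 relabellings gave at least the 8 across doses (highest other 1) and the 8 with a benchmark dose (highest other 0). Those relabellings did not keep the replicate numbers.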

How the results depend on the processing

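Alternatives for the blocked fit, and leaving out replicate numbers, were chosen after the result was seen. Settings not named kept each count within 1.5 times, and the block changed no other call than those in the counts given. The cause of each move was not tested. At raloxifene 20.1 µM the 18 calls became 9 at a level minimum of 50, 11 with quantile normalization, 242 with the block, 122 with array weights, 3 with only the 2 groups, 28 with DESeq2, and 11 to 17 without single libraries. At 2.01 µM the 0 became 4 with the block and 1 with only the 2 groups. At 0.201 µM it became 1 without a level filter and 3 with the block, at 0.0201 µM 1 without a filter, and at 0.00201 µM 19 with the block. With the block, the 242 became 149 with a 1.5-fold minimum and 117 to 225 without single replicates, and the 4 at 2.01 µM became 22 with DESeq2. At resorcinol 405 µM the 6 became 64 with the block, 12 with array weights, 16 with DESeq2 and 1 to 5 without single libraries, and the 64 became 130 with DESeq2 and 11 to 58 without single replicates. At 40.5 µM the 1 became 13 with the block, 0 with array weights, with only the 2 groups or with edgeR, 2 with DESeq2, and 0 to 9 without single libraries. The 13 became 3 with edgeR, 26 with DESeq2, and 0 to 42 without single replicates. The blocked counts at the lower raloxifene doses also moved: at 0.201 µM the 3 became 6 with a pseudocount of 0.5, 1 with quantile normalization, 5 with edgeR, 52 with DESeq2 and 0 to 8 without single replicates. At 0.00201 µM the 19 became 9 with a 1.5-fold minimum or no filter, 10 with a pseudocount of 0.5, 54 at a level minimum of 50, 8 with edgeR, 185 with DESeq2 and 0 to 12 without single replicates. The 0 at 0.0201 µM became 1 without a filter, the 0 at resorcinol 0.0405 µM became 1 with DESeq2, and the 4 at 2.01 µM became 0 to 5 without single replicates. Genes across doses became 352 and 44 with the block and 2 and 14 with a linear trend (raloxifene and resorcinol), 2 to 12 and 0 to 11 without single replicates. Genes with a benchmark dose became 7 and 4 at an adjusted p under 0.01, 116 and 36 with the block, 0 and 0 without the highest dose, and 2 to 10 and 0 to 10 without single replicates. Their medians became 10.0 and 11.4 µM at 2 SD, 6.04 µM for raloxifene with the block, and 3.58 to 4.47 and 4.26 to 5.08 µM without single replicates. Lists became 0 and 0 with an estimated correlation, with or without the block, 10 for resorcinol with the block, and 10 to 16 and 5 to 8 without single replicates. The next-dose correlations became 0.0626 and 0.0846 with split controls, and the overlap of compounds 3 with the block. Uncalled genes turned sign: DIO2 at 20.1 µM raloxifene (from a log2 change of 0.030 to -0.0054 with a pseudocount of 10, -0.056 with edgeR, -0.044 with DESeq2, -0.30, -0.074 and -0.088 without control 4, 20.1 µM replicates 1 and 5, and up to 0.18 without others), and ESR2 ENSDARG00000034181 at 405 µM resorcinol (from 0.14 to -0.10 and -0.0045 without control 1 and 405 µM replicate 3, up to 0.35 without others). No scaling moved the median of all genes by over 0.1. Depth limits the size of change that can be seen in the low odorant receptor and endocrine genes.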

Other observations

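The genes in this part were chosen after their values were seen, and calls are with the replicate block. At 20.1 µM raloxifene, irf1b, a transcription factor of the interferon response, rose in 5 of 5 pairs from 50.7 to 148 (adjusted p = 3.76e-06), as did gbp1 (log2 1.14), b2m (0.70), cxcl18a.1 (1.44), caspbl (0.94), tnfrsf1a (0.49) and FADD (0.96). The lamin gene LMNA (0.72) and the growth factor binding protein genes IGFBP1 (0.62) and igfbp1b (0.94) also rose. The glycolysis gene PKLR (-0.72) and the amino acid transporter genes SLC3A1 (-0.94) and SLC6A18 (-0.73) fell. The genes pth2 (1.09), gnrh2 (1.21), uts2d (1.32) and rln3a (0.52) rose, and the channel genes cnga4 (-1.61) and CNGA2 (-1.04) fell, as did s100s (-1.31) and OTOF ENSDARG00000020581 (-0.66).

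At 405 µM resorcinol, opn1mw2 was the only one called of 5 cone opsin genes tested: opn1mw1 changed by 0.34 (adjusted p = 0.325), OPN1SW by 0.57 (0.122), opn1sw2 by 0.05 and opn1lw2 by -0.50 (0.151, and called at 40.5 µM by -0.71, adjusted p = 0.0358). The photoreceptor transcription factor gene six7 rose (0.69, adjusted p = 0.0217), PDC ENSDARG00000017634 rose (0.61), and the chloride channel gene ano2b (-1.05), the retinal homeobox gene rx1 (-0.75) and SNX8 ENSDARG00000078057 (-1.03) fell. The deiodinase gene dio3b was at 251 ± 62.9 and 104 ± 30.998 (adjusted p = 0.0586).

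Digestive enzyme genes of the exocrine pancreas took 0.249% of reads in resorcinol controls and 0.420% at 405 µM (28 genes, median log2 0.93, higher in 5 of 5 pairs, against 0.84 as the highest of the other relabellings; adjusted p = 0.991 with an estimated correlation). For raloxifene the shares were 0.139% and 0.277% (27 genes, median 0.70, higher in 4 of 5 pairs, highest other 0.68; adjusted p = 0.990 with an estimated correlation). That median was 0.50 against the 2 lowest doses, and the medians against the control were -0.19 at 2.01 µM and 0.40 at 0.00201 µM.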
